A study of Mus musculus with 2 samples.

How the data were processed

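Total RNA sequencing of mouse limb at embryonic day 14.5 was used, with 2 libraries in 1 group, each with a table of genes and a table of transcripts. The build was mm10 with the GENCODE M4 annotation, and values were derived from alignments to the transcriptome, per the labels and the notes filed with each sample. The aligner, the quantification program, their versions and the strand of the libraries are not given in the sources used here. The labels name an extraction with a mirVana kit and a general protocol whose name refers to Smart-seq.

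The expected counts deposited by the authors are estimated reads per gene or transcript that need not be whole, as the file headers name them. The TPM values deposited by the authors are transcript abundances scaled to the same total in each library, as tested on the values, and that total includes spike-ins and mitochondrial genes. The FPKM values deposited by the authors were not used here. The percent of a gene's TPM held by a transcript was also deposited by the authors, per the file headers, as were posterior mean TPM values used in an alternative. Lengths, effective lengths and bounds of credibility intervals were deposited by the authors as well; the level of those intervals is not given in the sources used here. In the transcript tables the effective length, where above 0, was 99 nt below the length. Each table holds 1 replicate, per the notes filed with each sample. The labels give both samples the same donor identifier and the same pup and pregnancy numbers with different collection days. They were treated as separate pups, on which each SD over n = 2 and the coefficient of variation rest, and the closing section gives the sex-linked counts that bear on this. The tables list genes with Ensembl identifiers, 96 spike-in sequences, and 26248 features with numeric identifiers whose nature is not given in the sources used here.

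Gene symbols, types and positions were matched by Ensembl identifier to the reference annotation GENCODE M21 on GRCm38, the assembly that mm10 names. Of 43346 identifiers, 42462 had an entry and 884 had none.

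Analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. Expected counts were rounded to whole numbers for count tests, and spike-ins were left out of library sizes except where they served as the scaling. Detection required 1 TPM. The correlation used log2(TPM + 1), and ratios and list shifts used log2(TPM + 0.1), so that fold changes of low genes are understated. The biological coefficient of variation was the square root of edgeR's common dispersion with an intercept-only model after TMM normalization and edgeR's default filter. For 1 group of 2 libraries that filter asks for enough counts in both, so the Y-linked genes, at 0 in replicate 2, were not in that step or in edgeR's exact test.

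Differences between the libraries were tested per gene with a two-sided exact binomial test given the TMM library sizes, for genes with 10 or more counts in the sum, with Benjamini-Hochberg adjustment and a threshold of 0.05. That test covers counting error only. For edgeR's exact test the common dispersion was that of these same 2 libraries, so their typical difference counts as error. Gene lists were compared through the median log2 ratio of members with a mean of 1 TPM or more and its percentile among 10000 random lists of the same size matched on level in 20 bins. Each planned ratio was set beside the 95th percentile of the absolute log2 ratio between libraries of the 500 genes nearest in level. That percentile measures the spread of single genes between libraries, not error that differs between the genes of a ratio. Floors cover counting error only, because no molecular identifiers are recorded. The interval of the share of leading transcripts covers the sampling of genes only. A count of 0 allows up to 3 counts.

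The gene lists (36 lists, 403 genes), the 15 ratios, the 20 genes for transcripts, the comparisons with their tests and the alternatives, except where stated otherwise, were fixed before the data were examined. Tests of explanations are dated in the closing section. Named genes were the 3 members of highest mean TPM of each list, every gene of the ratios, every member of the sex-linked lists, the 15 nuclear protein-coding genes of highest mean TPM and the transcript genes. For library differences they were the 10 protein-coding genes of largest log2 ratio in each direction among those called, with a mean of 5 TPM or more and 50 or more counts in at least 1 library. List members below 1 TPM in both libraries could also be named. Other genes named in the text were chosen after their values were seen, and this is stated there.

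The alternatives were other TPM minimums, pseudocounts and count filters, DESeq2 size factors, total counts and spike-in counts as scalings, TMM-normalized counts in place of TPM, posterior mean TPM, each library alone, protein-coding genes only and edgeR's exact test at the common dispersion. Removing a linear trend on length and GC content from the list shifts was added after seeing the data, over 15059 genes, as was the binomial test on the genes of edgeR's exact test.

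The main steps were tested on simulated data. The binomial test, run on 19154 genes drawn from the libraries' means and sizes with counting error only, called 82.0% of 100 genes changed by a log2 fold of 1, 97.0% of 100 changed by 2, all drawn from genes with 20 or more expected reads, and 0.0686% of 18954 unchanged genes. For 2 simulated unchanged libraries with a coefficient of variation of 0.1 the estimate was 0.100 over 17136 genes. A contractile list moved by −0.5 had a mean median of −0.51 over 20 simulations.

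The depth was 34193161 and 32879425 expected counts in replicates 1 and 2. Of 12852 genes with 100 or more counts in both libraries, 34 had identical counts, and the libraries were kept as separate replicates.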

Results

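Total RNA from the limbs of mouse embryos of strain B6NCrl at embryonic day 14.5 was profiled by RNA sequencing in 2 libraries, which the labels give as biological replicates 1 and 2. Each library was made from 10 ng of RNA longer than 200 nt, with synthetic spike-in RNAs added. The labels describe each sample as the 4 limbs of a pup, collected on different days, and also give the sex of each as pooled. Both carry the same donor identifier and the same pup and pregnancy numbers. All samples belong to 1 group, so no comparison between conditions exists, and levels are given as the mean ± SD over n = 2 libraries. A difference between the libraries has 1 library on each side and no replicate check, and a test on their reads compares those libraries, not conditions. The total was 34193161 expected counts in replicate 1 and 32879425 in replicate 2.

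The most abundant nuclear protein-coding RNAs were globin, cytoskeletal and translation RNAs. Alpha globin Hba-a2 led at 9674 ± 2567 TPM (the unit of transcript abundance in the tables, SD, n = 2), followed by the actin gene Actb at 5192 ± 44.0 TPM and the elongation factor gene Eef1a1 at 4976 ± 128 TPM. Beta globin Hbb-bs stood at 4544 ± 1465 TPM, the ferritin gene Ftl1 at 3738 ± 138 TPM, Hba-a1 at 3657 ± 1010 TPM and Hbb-bt at 3653 ± 1094 TPM. Also among the 15 highest were Rpl41, Ppia, Rps19, the histone gene Hist1h2ap and Ubb, at 3657 ± 194, 3613 ± 92.4, 2828 ± 96.0, 2740 ± 125 and 2671 ± 115 TPM. The collagen genes Col3a1 and Col1a1 were also among the 15 highest, at 2236 ± 215 and 2075 ± 191 TPM, as was the histone variant gene H3f3a at 2083 ± 29.6 TPM. These 15 genes together held 4.12 ± 0.390% of counts. Reads of the near-identical pairs Hba-a1 with Hba-a2 and Hbb-bs with Hbb-bt cannot be assigned with certainty to 1 member, and the summed levels were 13331 ± 3577 and 8197 ± 2560 TPM.

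At 1 TPM or more in both libraries, 14739 of 43346 annotated genes were detected, of which 13191 were protein-coding and 198 were long intergenic noncoding genes. A further 483 genes reached 1 TPM in replicate 1 alone and 640 in replicate 2 alone, and 53 of these were at or above 5 TPM in the library that had them. Protein-coding genes held 88.9 ± 0.0370% of counts and genes of the mitochondrial chromosome 1.65 ± 0.0160%. Gm42418 and Gm26917, neighbours on chromosome 17 that the reference annotation types as long intergenic noncoding genes, held 2.32 ± 0.0580%. The source of their reads was not tested.

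Expression of the Hox genes, the transcription factor genes that pattern the limb from shoulder to digit, lay mostly in the 5-prime part of the HoxA and HoxD clusters. Of 39 Hox genes, 24 reached 1 TPM in both libraries. Hoxa10 (mm10, chromosome 6, 52231197 to 52240854) was the highest at 103 ± 17.2 TPM, ahead of Hoxa9 at 33.1 ± 3.34 TPM and Hoxa11 at 27.6 ± 4.33 TPM. In the HoxD cluster the level was highest at Hoxd13 (chromosome 2, 74668310 to 74671599) with 48.1 ± 8.58 TPM, followed by Hoxd12 with 35.1 ± 7.86 TPM and Hoxd11 with 19.8 ± 4.65 TPM. HoxB and HoxC genes were low, with Hoxb2 at 3.82 ± 0.877 TPM and Hoxc13 at 5.29 ± 0.863 TPM as the highest of each cluster, Hoxb7 at 2.56 ± 1.22 TPM, Hoxb9 at 0.880 ± 0.0990 TPM, Hoxc10 at 4.53 ± 0.0707 TPM, Hoxc12 at 3.19 ± 0.120 TPM and Hoxb13 listed at 0 in both libraries.

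The summed 5-prime HoxA and HoxD genes exceeded the 3-prime genes of the same clusters by 3.46 ± 0.36 on the log2 scale (SD, n = 2) and the 5-prime HoxC genes by 4.32 ± 0.17. Both ratios were far larger than the difference between the libraries of genes at the same level, of which 95% lay under 0.35 and 0.46. The summed group 13 genes of both clusters exceeded the group 11 genes by 0.42 ± 0.02, against 0.33 for genes at the same level. This came from the HoxD cluster, since Hoxa13, at 15.4 ± 4.39 TPM, was below Hoxa11. With 2 libraries an exact sign-flip test cannot go below p = 0.5, so none of the planned ratios was given a p-value.

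**Figure D1:**
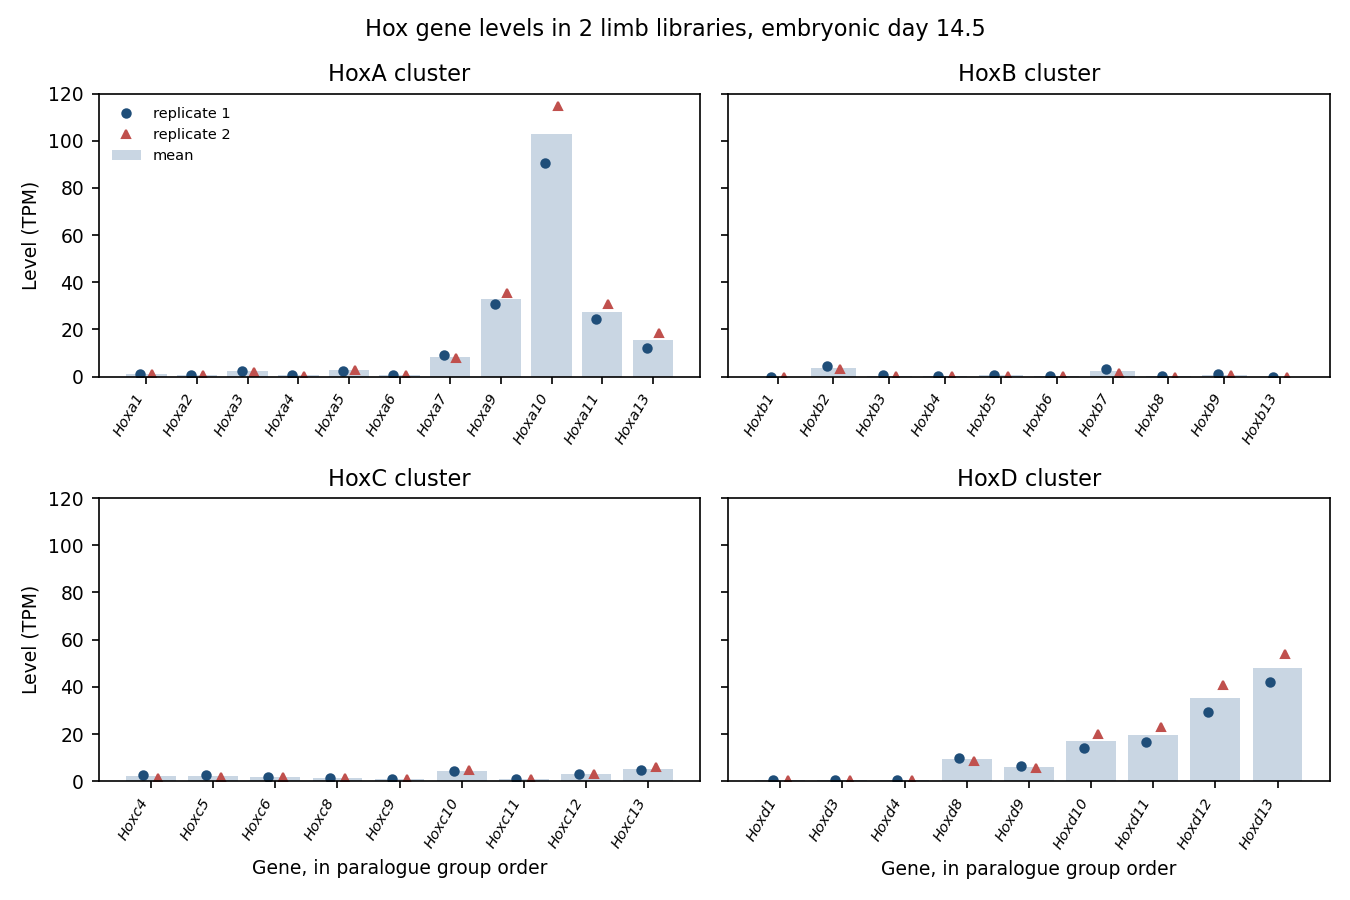
Level in TPM of each gene of the 4 Hox clusters, in paralogue group order; bars are means of 2 limb libraries, circles replicate 1 and triangles replicate 2. Hoxa10 reached 103 ± 17.2 TPM and Hoxd13 48.1 ± 8.58 TPM, while no HoxB or HoxC gene had a mean above 5.29 TPM.

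Regulators of forelimb and hindlimb identity were both present. The forelimb gene Tbx5 stood at 17.6 ± 3.20 TPM and the hindlimb genes Tbx4 and Pitx1 at 13.7 ± 2.43 and 56.3 ± 11.5 TPM. The log2 ratio of Tbx5 over Tbx4 was 0.36 ± 0.01, less than the 0.48 under which 95% of genes at that level differed between the libraries, and that of Tbx5 over Pitx1 was −1.67 ± 0.03, against 0.43. Among 26 patterning genes, 23 reached 1 TPM in both libraries, led by Msx1 at 111 ± 24.2 TPM, Prrx1 at 94.3 ± 10.3 TPM and Prrx2 at 80.2 ± 10.8 TPM. Shh, the early posterior organiser signal of the limb bud, stood at 0.0250 ± 0.0354 TPM, and the apical ridge factors Fgf8 and Fgf4 at 0.290 ± 0.0849 and 0.930 ± 0.325 TPM. Of 17 listed genes of hedgehog, FGF, WNT and BMP signalling, 17 reached 1 TPM in both libraries, with Fgfr1 at 115 ± 6.91 TPM, Fgfr2 at 110 ± 9.26 TPM and Wnt5a at 92.1 ± 12.5 TPM.

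Cartilage genes, the longest of the skeletal lists, had the highest summed level of them, 1818 TPM, with Col1a1 counted among the fibroblast genes. All 19 cartilage genes reached 1 TPM in both libraries, with a median of 47.6 TPM, and Col2a1, the main collagen of cartilage, stood at 585 ± 2.56 TPM, Col9a3 at 277 ± 14.0 TPM and Cnmd at 142 ± 16.6 TPM. Col2a1 exceeded Col10a1, the collagen of hypertrophic cartilage, by 5.51 ± 0.13 on the log2 scale (45.5-fold), and was below Col1a1 by a log2 ratio of −1.82 ± 0.14. The cartilage regulator gene Sox9 exceeded the bone regulator gene Runx2 by 2.71 ± 0.17, at 88.6 ± 18.5 against 13.3 ± 1.22 TPM. Each of these 3 ratios was larger than the 0.45, 0.25 and 0.50 under which 95% of genes at the same levels differed between the libraries.

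The lists of hypertrophic cartilage and bone-forming cells had lower medians, 11.8 and 6.48 TPM, although Spp1 and Ibsp stood above the cartilage median. Spp1 stood at 126 ± 34.4 TPM, Pth1r at 74.3 ± 1.72 TPM and Col10a1 at 12.8 ± 1.07 TPM. Of 12 genes of bone-forming cells, 10 reached 1 TPM in both libraries, led by Ibsp at 176 ± 36.9 TPM, Dlx5 at 27.2 ± 0.375 TPM and Alpl at 20.9 ± 0.933 TPM. Of 8 genes of bone-resorbing cells, 4 did, led by Ctsk at 71.6 ± 11.8 TPM, Acp5 at 15.2 ± 3.39 TPM and Mmp9 at 12.8 ± 3.12 TPM. Joint markers were led by Osr2 at 94.9 ± 14.3 TPM, Gdf5 at 58.3 ± 12.1 TPM and Erg at 15.4 ± 1.47 TPM, and tendon markers by Kera at 149 ± 17.8 TPM, Tnmd at 130.0 ± 7.15 TPM and Fmod at 59.4 ± 2.35 TPM.

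Muscle genes included embryonic, perinatal, slow and fast isoforms of the contractile apparatus. Of 26 contractile genes, 24 reached 1 TPM in both libraries, led by the cardiac and skeletal actin genes Actc1 at 830.2 ± 191 TPM and Acta1 at 624 ± 207 TPM and by Myl1 at 443 ± 118 TPM. The embryonic myosin heavy chain gene Myh3 exceeded the perinatal gene Myh8 by 1.52 ± 0.07 on the log2 scale and the slow gene Myh7 by 2.61 ± 0.12, while the adult fast genes Myh2 and Myh4 stood at 0.260 ± 0.0424 and 0.185 ± 0.134 TPM and Myh1, named here after its value was seen, at 1.48 ± 0.523 TPM. Slow troponin Tnni1 exceeded fast troponin Tnni2 by 1.80 ± 0.24, and Acta1 was below Actc1 with a log2 ratio of −0.43 ± 0.15. These 4 ratios lay beyond the 0.33, 0.42, 0.27 and 0.23 for genes at their levels. Myogenic regulators were led by Myog at 103 ± 17.3 TPM, Mymk at 45.5 ± 12.5 TPM and Myod1 at 34.7 ± 3.10 TPM.

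**Figure D2:**
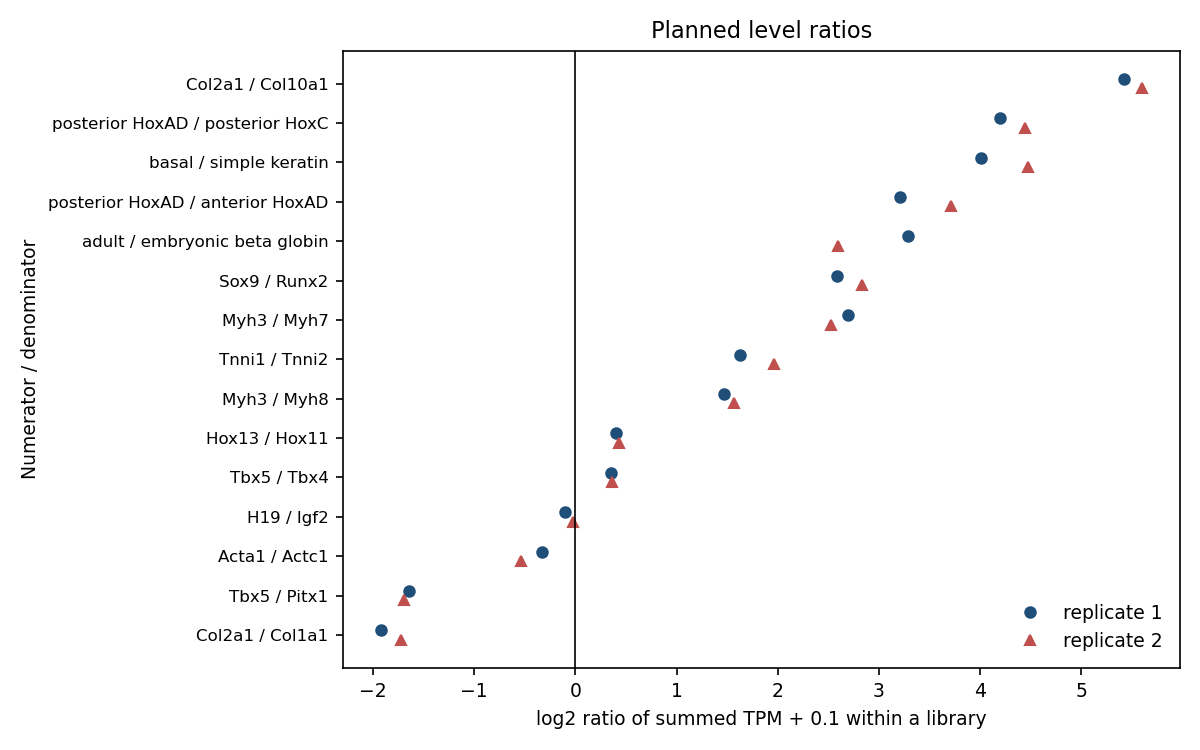
Log2 ratio of the summed TPM + 0.1 of numerator over denominator genes for 15 ratios, with replicate 1 as circles and replicate 2 as triangles. The cartilage ratio Col2a1 over Col10a1 was the highest at 5.51 ± 0.13, and adult over embryonic beta globin lay at 3.28 in replicate 1 and 2.59 in replicate 2.

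Red blood cell genes held the highest level of any cell type list, with a summed 22776 TPM. The adult beta globins exceeded the embryonic ones by 2.94 ± 0.49 on the log2 scale, which was 9.74-fold in replicate 1 and 6.04-fold in replicate 2. The embryonic beta globin Hbb-y stood at 1036 ± 21.5 TPM. Epidermal genes were led by Perp at 420.5 ± 74.6 TPM, the basal keratin gene Krt14 at 380.3 ± 8.61 TPM and Sfn at 207 ± 28.6 TPM, and stratified keratins Krt5 and Krt14 exceeded simple keratins Krt8 and Krt18 by 4.24 ± 0.33. The ratios of beta globins and keratins lay beyond the 0.25 and 0.35 for genes at the same levels.

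Genes listed for other cell types were also detected, which does not by itself show that each cell type was present. Fibroblast genes had a summed 7468 TPM and were led by Col3a1 and Col1a1 and by Col1a2 at 1447 ± 94.9 TPM. All 12 endothelial genes reached 1 TPM, led by Egfl7 at 81.9 ± 2.43, Esam at 35.5 ± 2.18 and Pecam1 at 30.7 ± 0.665 TPM, and 9 of 10 genes of smooth muscle and pericytes did, led by Acta2 at 220.1 ± 43.4, Pdgfrb at 34.3 ± 3.55 and Cspg4 at 21.8 ± 1.29 TPM. Leukocyte genes were led by Lyz2 at 80.4 ± 5.55, Fcer1g at 68.0 ± 3.18 and C1qb at 62.6 ± 0.247 TPM, and Schwann cell and melanoblast genes by Erbb3 at 15.6 ± 0.870, Fabp7 at 7.28 ± 0.856 and S100b at 7.08 ± 0.778 TPM. Of 7 neuronal genes 2 reached 1 TPM in both libraries and 4 were under it in both, and they were led by Stmn2 at 6.29 ± 0.948, Tubb3 at 2.73 ± 0.163 and Syt1 at 1.18 ± 0.438 TPM, while of 6 adipocyte genes 3 reached it and 3 were under it in both, led by Cebpa at 9.72 ± 0.594, Fabp4 at 9.45 ± 3.66 and Pparg at 1.54 ± 0.269 TPM. Among the genes under 1 TPM, the adipocyte gene Adipoq stood at 0.2 ± 0.0141 TPM, and the adipocyte genes Plin1 and Lep and the neuronal gene Neurod1 were listed at 0. Markers of neighbouring organs were low, and of these Tnni3 alone reached 1 TPM in both libraries. Liver genes were led by Apoa1 at 0.920 ± 0.113 TPM with Alb at 0.530 ± 0.0424 and Afp at 0.120 ± 0.141, heart genes by Tnni3 at 2.31 ± 0.255 TPM with Myl7 at 0.735 ± 0.0354 and Nppa at 0.725 ± 0.0919, and lung genes by Sftpc at 0.130 ± 0.184 TPM with Nkx2-1 lower still and Sftpb listed at 0.

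Imprinted genes were among the most abundant lists, with 21 of 21 members at 1 TPM in both libraries. Gnas stood at 1820.0 ± 10.1 TPM, Mest at 1762 ± 85.8 TPM and Cdkn1c at 1235 ± 51.5 TPM. The log2 ratio of H19 over Igf2, neighbours on chromosome 7 expressed from opposite parental alleles, was −0.06 ± 0.06, below the 0.25 for genes at that level, at 1077 ± 23.0 and 1126 ± 19.4 TPM. All 16 cell cycle genes were detected, led by Cdk1 at 316 ± 5.80, Birc5 at 209 ± 4.86 and Pcna at 178 ± 3.07 TPM. Immediate early genes were led by Ier2 at 52.3 ± 2.14, Jun at 41.0 ± 2.98 and Dusp1 at 20.3 ± 1.49 TPM, and hypoxia genes by Ldha at 1172 ± 73.1, Pgk1 at 231 ± 7.83 and Slc2a1 at 109.8 ± 5.30 TPM.

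Noncoding RNAs and histone RNAs without a poly(A) tail were present. Malat1 stood at 3303 ± 467 TPM, Rn7sk at 473 ± 3.60 TPM and Rpph1 at 93.9 ± 5.00 TPM. Of 23 replication-dependent histone genes, 22 reached 1 TPM in both libraries with a median of 10.7 TPM, led within this list, which does not hold Hist1h2ap, by Hist1h4d with a mean of 265 TPM, Hist1h2ae at 175 ± 3.66 and Hist1h3i at 113 ± 11.1 TPM, although reads of these similar genes can be shared between copies. Histone variants were led by H3f3a, by H3f3b at 1469 ± 48.9 TPM and by H2afz at 1099.5 ± 11.7 TPM. The mitochondrial protein-coding genes were led by mt-Atp6 at 5908 ± 269, mt-Atp8 at 5183 ± 33.9 and mt-Cytb at 3327 ± 23.0 TPM. The unprocessed pseudogenes Gm28437 and Gm28661 on chromosome 1 stood at 8717 ± 48.1 and 2191 ± 76.3 TPM. Whether they share reads with mitochondrial genes was not tested. The order of the mitochondrial genes and the percent of counts given above for their chromosome are therefore uncertain.

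Levels in the libraries were close. Across 15862 genes at 1 TPM or more in at least 1 library, Pearson's r of log2(TPM + 1) was 0.984 and Spearman's rho 0.986, where genes are not independent replicates. Of 15307 genes with a mean of 1 TPM or more, 97.4% lay within a 2-fold difference, with a median log2 ratio of replicate 2 over replicate 1 of 0.07. The biological coefficient of variation from edgeR's common dispersion was 0.0992 over 16920 genes.

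Muscle, red blood cell and epidermal genes were lower in replicate 2, and genes of limb patterning and Hoxd10 to Hoxd13 were higher. By an exact binomial test on counts with Benjamini-Hochberg adjustment, 24 of 26 contractile genes were lower in replicate 2 and 1 was higher, with the same counts adjusted over the list alone. With the spread of the typical gene included, by edgeR's exact test at the common dispersion, 4 of these 26 were called. The median log2 ratio of the list was −0.52, at percentile 0 among 10000 random lists of the same size and level. The exception was the adult myosin gene Myh4, named here after its value was seen, at 0.0900 TPM in replicate 1 and 0.280 TPM in replicate 2. Of 10 myogenic regulators 8 were lower and none higher, including Myog at 115 and 90.5 TPM in replicates 1 and 2, with a list median of −0.50 at percentile 0 and the same counts adjusted over the list alone, but edgeR's exact test called 0 of the 10.

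Of 13 red blood cell genes, 9 were lower in replicate 2 and none was higher, also adjusted over the list alone, with a median of −0.56 at percentile 0, and edgeR's exact test called 3 of the 12 it tested. The adult globins took 0.869% of counts in replicate 1 and 0.560% in replicate 2, while the embryonic globin Hbb-y, at 1021 and 1051 TPM, was not called (adjusted p = 0.190 by the exact binomial test). Of 17 epidermal genes, 15 were lower and none higher, also adjusted over the list alone, with a median of −0.29 at percentile 0, but edgeR's exact test called 0 of the 16 it tested. Bone genes were lower as well. Of 12 genes of bone-forming cells, 4 were lower (5 adjusted over the list alone), with a median of −0.30 at percentile 0.0300. Of 8 genes of bone-resorbing cells, 3 were lower, with a median of −0.40 at percentile 0.15, and of 6 genes of hypertrophic cartilage 4 were lower, with a median of −0.17 at percentile 0.880, both with the same counts adjusted over the list alone. None of these 3 lists had a higher gene, and none had a call by edgeR's exact test.

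Of 26 limb patterning genes, 14 were higher in replicate 2 and 1, Meis1, named here after its value was seen, was lower (16 and 2 adjusted over the list alone), with a median log2 ratio of 0.26 at percentile 100. These calls rest on counting error only, and edgeR's exact test called 0 of the 24 it tested. Msx1 was at 93.6 TPM in replicate 1 and 128 TPM in replicate 2, Pitx1 at 48.2 and 64.5 TPM and Tbx5 at 15.3 and 19.9 TPM. In the HoxD list 4 of 9 genes, Hoxd10 to Hoxd13, were higher and none was lower (4 and 1 adjusted over the list alone), with a median of 0.41 at percentile 99.99. In the HoxA list Hoxa10, Hoxa11 and Hoxa13 were higher and none of 11 was lower (4 and 2 adjusted over the list alone), with a median of 0.19 at percentile 92.3. By edgeR's exact test 0 of 9 HoxD and 0 of 10 HoxA genes were called. Of 7 joint genes 4 were higher, with the same count adjusted over the list alone, and a median of 0.31 at percentile 98.975, and of 17 signalling genes 7 were higher and 1 lower (8 and 2 adjusted over the list alone), with a median of 0.21 at percentile 99.8, and neither list had a call by edgeR's exact test. With TMM-normalized counts in place of TPM the medians of the signalling and limb patterning lists were 0.12 and 0.17, still above the central 95% of random lists. The ratio of 5-prime to 3-prime HoxA and HoxD genes was 0.51 higher in replicate 2 on the log2 scale, beyond the 0.35 for single genes at that level. A ratio carries the spread of both its sides, so that value is a lenient bound for it.

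Shifts were also seen in other lists. Fibroblast genes had a median of −0.11, below the central 95% of random lists, with 2 genes higher and 7 lower. The same held for smooth muscle and pericytes, with a median of −0.13, 1 gene higher and 6 lower (1 and 7 adjusted over the list alone), and for Schwann cells and melanoblasts, with −0.22 and 2 genes lower, although without the filter on low values their median of −0.13 lay inside that range. Adipocyte genes had a median of −0.34 with 1 gene lower, Fabp4 (2 adjusted over the list alone), but −0.22 with a pseudocount of 1 and −0.06 without the filter, both inside the range. Cartilage had a median of −0.03 with 5 higher and 11 lower, and immediate early genes of −0.09 with 3 lower (4 adjusted over the list alone). With TMM-normalized counts the medians of cartilage and immediate early genes were −0.09 and −0.16. Those of fibroblasts and of smooth muscle and pericytes were −0.18 and −0.20. Histone variants had a median of 0.08 at percentile 97.55, with 2 genes higher and 2 lower. That median lay inside the range without the filter, with TMM-normalized counts and without the length and GC trend.

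Medians within the central 95% of random lists were found for HoxC (−0.04, 2 genes lower), tendon (0.11, 2 higher and 2 lower), endothelium (−0.01, 3 lower), leukocytes (0.01, 4 lower) and neurons (0.12, with Syt1 higher). They were also found for the cell cycle (0.05, 4 higher and 1 lower), imprinted genes (−0.04, 2 higher and 15 lower), hypoxia (−0.07, 4 lower), noncoding RNAs (−0.02, 1 higher and 1 lower), replication-dependent histones (0.15, 2 higher and 1 lower, or 1 and 1 adjusted over the list alone) and mitochondrial genes (0.00, 4 higher and 9 lower). Where no second count is given for these lists, that adjusted over the list alone was the same. HoxB, with 3 genes lower, liver, with Afp lower, and heart and lung, with no call, had fewer than 3 members at 1 TPM and no percentile.

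**Figure D3:**
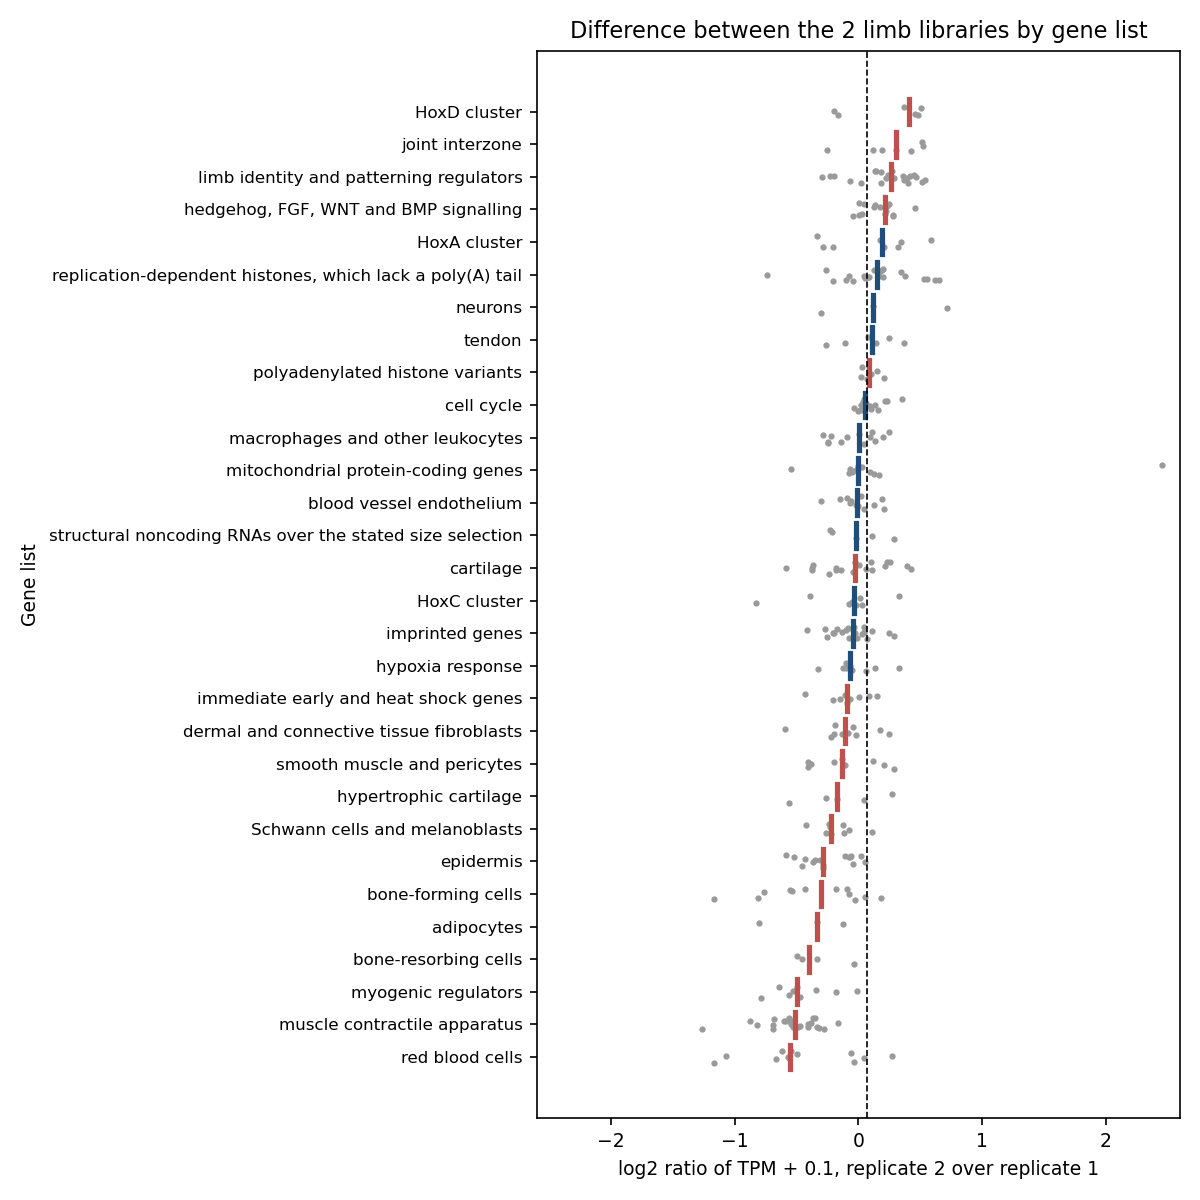
Log2 ratio of TPM + 0.1, replicate 2 over replicate 1, for genes with a mean of 1 TPM or more in each list with 3 or more of them; points are genes, bars list medians, red where the median lay outside the central 95% of 10000 random lists, and the dashed line is the median of all genes, 0.07. Contractile genes lay at −0.52 and the HoxD genes at 0.41, and the Y-linked list is not drawn.

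In all, 19 of 31 lists lay outside the central 95% of random lists, 14 of them low and 5 high, where lists of unrelated genes give 1.55 by chance. Members of a list are often expressed in the same cells and move together, so that number is no chance count for lists like these, and the Y-linked list is among the 31. Over all genes the exact binomial test called 5275 of 19153 genes, 2528 higher and 2747 lower in replicate 2. The share of calls that were higher was 47.9%, against 43.0% with DESeq2 size factors, 59.9% with scaling by total counts and 69.0% with scaling by the spike-ins. This test knows counting error only. When the spread of the typical gene between the libraries was included, through edgeR's exact test at the common dispersion, 113 of 16920 genes were called, 30 higher and 83 lower. The filter of that test left out the Y-linked genes. The common dispersion came from these same 2 libraries, so the test counts their typical difference as error. A gene it did not call is not thereby shown to be alike in both. Among the listed genes the calls included Acta1, Tnnt3, Tnni2, Ckm, Hbb-bs and Slc4a1 on the lower side and Xist and mt-Nd4l on the higher side. No gene was called in any list other than the contractile, red blood cell, mitochondrial and X inactivation lists.

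Beyond the sex-linked genes, protein-coding genes with a mean of 5 TPM or more that were lowest in replicate 2 relative to replicate 1 included leukocyte, muscle and epidermal genes. The adjusted p of edgeR's exact test assume the spread of the typical gene, which these genes need not have. S100a8 (chromosome 3, 90668978 to 90670035), which encodes a calcium-binding protein of neutrophils, was 4.20-fold lower in replicate 2 (35.0 and 8.27 TPM; adjusted p = 3.77e-10 by edgeR's exact test), and its partner S100a9 was 3.05-fold lower (adjusted p = 3.27e-06). Ckm, the creatine kinase of muscle (chromosome 7, 19404776 to 19422841), was 2.40-fold lower (52.6 and 21.9 TPM; adjusted p = 8.87e-07), Myoz1 2.48-fold lower (adjusted p = 0.000351) and Calm4 2.39-fold lower (adjusted p = 5.75e-06). Dhrs7c was 2.77-fold lower by the binomial test, with an adjusted p of 0.0785 by edgeR's exact test.

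The largest of these differences was on the higher side, in mt-Nd4l. Cacng4 was 2.19-fold higher in replicate 2 (adjusted p = 0.0157 by edgeR's exact test). The other genes taken by the same rule were mt-Nd4l, Tmem254b, Gm20431, Gm21887, Xlr3b and Gm14434, with folds of 5.48, 3.99, 2.93, 2.20, 2.17 and 1.99, and Hist1h2ah, 5031439G07Rik and Eif4ebp3, with folds of 2.38, 2.22 and 2.17. The latter 3 had adjusted p of 0.0777, 0.169 and 0.0514 by edgeR's exact test. Many of these belong to families of similar or overlapping copies and are uncertain. Gm21887 and Xlr3b lie on the X chromosome, and whether their difference goes with that of the sex-linked genes was not tested. The sum of Tmem254a, Tmem254b and Tmem254c was 69.5 TPM in replicate 1 and 67.2 TPM in replicate 2, and that of mt-Nd4l and mt-Nd4 was 1381 and 1483 TPM.

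Y-linked genes had counts in replicate 1 alone, and Xist was detected almost entirely in replicate 2. Ddx3y (chromosome Y, 1260771 to 1286629) had 2868 counts in replicate 1 and 0 in replicate 2, and Eif2s3y had 1320 and 0, Kdm5d 1320 and 0 and Uty 1123 and 0. Set against the 3 counts that a count of 0 allows per library, they were at least 939-fold, 432-fold, 432-fold and 368-fold lower in replicate 2. Xist, the RNA that coats the inactive X chromosome (chromosome X, 103460366 to 103483254), stood at 0.0300 TPM in replicate 1 and 79.0 TPM in replicate 2, a log2 ratio of 9.25. Tsix overlaps Xist on the other strand, and without a stated strand its 2.55 and 347 counts cannot be told from those of Xist. Usp9y and Zfy1 had 0 counts in both libraries. The 6 Y-linked genes had a list median of −7.72 over the 4 at 1 TPM or more, which depends on the pseudocount. With each at its bound, the median was at least 432-fold lower.

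The leading transcript of a gene was mostly shared. Among 10023 genes at 1 TPM or more in both libraries with several annotated transcripts, 91.2% had the same leading transcript in both (95% exact binomial interval 90.6 to 91.7%, which treats genes as independent draws and leaves out the error of each gene's reads). Of 20 genes chosen beforehand, 16 did. The pyruvate kinase gene Pkm had 92.7 ± 1.07% of its TPM in Pkm-201, Actn1 87.1 ± 1.99% in Actn1-201, Col9a1 75.6 ± 2.12% in Col9a1-202, Col2a1 66.1 ± 5.75% in Col2a1-202, Tnnt2 62.4 ± 1.96% in Tnnt2-207, Tnc 59.2 ± 1.19% in Tnc-204, Mef2c 57.6 ± 4.16% in Mef2c-202 and Col11a1 52.6 ± 1.10% in Col11a1-201. The leading share was lower in Fgfr1 (47.0 ± 0.134%), Sox6 (46.2 ± 0.170%), Cd44 (44.1 ± 1.13%), Fgfr3 (41.7 ± 6.11%), Fgfr2 (32.0 ± 2.64%), Tnnt3 (28.7 ± 2.28%), Sox5 (22.4 ± 5.26%) and Mbnl1 (22.2 ± 0.467%). Fn1, Tpm1, Tpm2 and Runx2 had different leading transcripts in the libraries. For Fn1 this was a near tie, with 40.3% in Fn1-201 and 40.6% in Fn1-202 in replicate 1. Whether any of these changes exceeds the error of the transcript estimates was not tested.

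Spike-in recovery was similar in both libraries. They took 5.29% of counts in replicate 1 and 5.20% in replicate 2. Of 96 spike-in sequences, 82 had a count in both libraries, and across them Pearson's r of log2 counts was 0.988 and Spearman's rho 0.991.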

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

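The tests of a pool of both sexes, of a length or GC trend, of proximal tissue for the Hox genes and for the globins, and of developmental progress were chosen only after the result was seen, and those of a sex difference and of polyadenylated RNA were written earlier.

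Counts appeared in data that no comparison used. The 26248 features with numeric identifiers, of median length 73 nt, had 17 counts in replicate 1 and 27 in replicate 2, which came from 6 and 5 of these features. The 3 counts that a count of 0 allows apply to a single feature, so they set no bound for these sums.

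The labels give each library as pooled male and female, but the levels of the sex-linked genes separated them. Ddx3y, Eif2s3y, Kdm5d and Uty together had 6631 counts in replicate 1 and 0 in replicate 2, which argues against a pool of both sexes in replicate 2 and against 1 pup as the source of both libraries, although the labels give both the same pup number and donor. The log2 ratio of Xist was 9.25, with 11.45 counts in replicate 1 and 29957 in replicate 2, which argues against a pool of both sexes in replicate 1. Together these counts point to a male pup for replicate 1 and a female pup for replicate 2. The sex was inferred from these reads alone, with 1 library on each side. X-linked protein-coding genes had a median log2 ratio of 0.06 over 469 genes against 0.07 over 12939 autosomal genes, while Kdm5c, Eif2s3x, Kdm6a and Ddx3x, known to escape X inactivation and picked after the values were seen, had log2 ratios of 0.73, 0.79, 0.72 and 0.33, with 57 X-linked genes ranked above the lowest of the 4.

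Muscle, red blood cell and epidermal genes were lower and limb patterning genes higher in replicate 2 by a test that knows counting error only. By edgeR's exact test, whose dispersion came from these same 2 libraries, 0 of 16 epidermal, 0 of 24 limb patterning and 0 of 10 myogenic genes were called. A length or GC trend is argued against as the whole cause, since the contractile list kept a median of −0.50 after the trend was removed. More proximal tissue in replicate 1 was not decided for the Hox genes: the median of 7 distal genes lay 0.66 above that of 7 proximal genes (0.46 and −0.21), but the distal genes were those already called higher, while adult over embryonic beta globin changed by −0.69 where genes at that level stay within 0.25, which argues against proximal tissue for the globins. A pup further along in development in replicate 1 stays open. Of 6 ratios with a developmental order, picked and then revised after their values were seen, 5 were later in replicate 1. Of these, 2 changed by more than genes at their levels. Basal over simple keratin was later in replicate 2 by 0.46, beyond its 0.35. By contrast, all 12 late epidermal differentiation genes with a mean of 1 TPM or more were lower in replicate 2, with a median of −0.84. That group was also made after the values were seen, so the epidermal genes do not decide the question. Collection day and the level of sex-linked genes coincide with the libraries, the design gives no biological comparison, and the cause for the muscle and epidermal genes is not settled.

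Replication-dependent histone RNAs, which lack a poly(A) tail, had a median level of 10.685 TPM. That level argues against libraries of polyadenylated RNA alone, in which a median under 1 TPM had been predicted.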

How the results depend on the processing

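Removing the length and GC trend and the binomial test on the genes of edgeR's exact test were chosen only after the data were seen, and the other alternatives were fixed earlier. No paired analysis was possible because there is 1 group. Detection and the total of binomial calls under other scalings and filters stayed within 1.5 times the reported value. So did the spike-in count and the number of lists outside the random range, which was 18 to 21. The calls higher in replicate 2 did not, at 2528 as reported and 4167 with spike-in scaling. Those lower in replicate 2 were 2747 and 1871. Detected genes were 15379 and 15222 with 1 library alone. With edgeR's exact test the calls were 113 of 16920 genes in place of 5275 of 19153. The binomial test on those 16920 genes gave 5034 calls, so the smaller set of genes accounts for little of the change. The correlation was 0.952 and 0.900 with pseudocounts of 0.1 and 0.01, 0.994 without a filter and 0.993 with TMM-scaled counts. The coefficient of variation was 0.115 without a filter and 0.0887 for protein-coding genes. The ratios Tbx5 over Tbx4 and Tbx5 over Pitx1 were 0.34 and −1.62 with a pseudocount of 1, and the shared leading transcripts were 94.1% at 10 TPM or more. For these the cause was not tested, and a correlation or coefficient of variation was taken as moved where its second decimal changed.

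Among the 31 list shifts, 30 kept their side of the random range with a pseudocount of 1 and with TMM-normalized counts, 27 without a filter and 27 without the trend. Contractile genes had 24 lower calls under each of the 4 scalings and limb patterning genes between 13 and 16 higher, whereas histone variants had 2 higher and 3 lower with DESeq2 size factors and 4 higher and 0 lower with spike-in scaling. Histone variants fell inside the random range under 3 alternatives, adipocytes under 2 (−0.22 with a pseudocount of 1 and −0.06 without a filter) and Schwann cells and melanoblasts without a filter (−0.13). Imprinted genes came to lie outside it without a filter and without the trend (−0.04 in both), and endothelium (−0.03) and replication-dependent histones (0.18) without the trend. With TMM-normalized counts the 19 medians outside the range moved by a median of −0.07 and 7 changed by over 1.5 times. Among these, signalling moved from 0.21 to 0.12, limb patterning from 0.26 to 0.17, fibroblasts from −0.11 to −0.18, smooth muscle and pericytes from −0.13 to −0.20, immediate early genes from −0.09 to −0.16, cartilage from −0.03 to −0.09 and histone variants from 0.08 to 0.01. HoxA, inside the range in both, moved from 0.19 to 0.11. Without the trend cartilage moved to −0.07. At the depth of these libraries, the only depth simulated, the binomial test called 82.0% of simulated genes changed by a log2 fold of 1.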

Other observations

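The groups below were made after the values were seen, and their tests were chosen only after the result was seen. Genes of late epidermal differentiation were lower in replicate 2. Of 14 such genes, 12 had a mean of 1 TPM or more, all 12 of these had a log2 ratio below 0, and the median was −0.84. The 14 include Calm4, named above among the largest decreases, and Krt1, Krt10 and Lor of the epidermal list, so these values in part restate earlier ones. The exact binomial test called 13 of the 14 and edgeR's exact test 9. Krtdap stood at 1101 TPM in replicate 1 and 636 TPM in replicate 2 (adjusted p = 0.0116 by edgeR's exact test), Krt77 at 25.2 and 12.6 TPM (adjusted p = 0.000333) and Krt6a at 20.5 and 10.8 TPM (adjusted p = 0.00257). The basal keratin Krt14 stood at 386 and 374 TPM (adjusted p = 1.28e-06 by the exact binomial test) and was not called by edgeR's exact test.

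Genes of neutrophil granules and mast cells were lower too, in part. Of 10 neutrophil genes 7 had a mean of 1 TPM or more, 6 of them with a log2 ratio below 0, and the median was −1.45. The 10 include S100a8 and S100a9, named above among the largest decreases, so these values in part restate earlier ones. Ngp stood at 4.84 and 1.76 TPM and Camp at 4.87 and 1.30 TPM in replicates 1 and 2, with adjusted p of 0.00141 and 0.00457 by edgeR's exact test, whereas Mpo was at 1.32 and 1.29 TPM and Prtn3 at 4.54 and 6.29 TPM. Of 8 mast cell genes 7 had a mean of 1 TPM or more, 5 of them below 0. The protease genes Tpsb2 and Cma1 stood at 64.4 and 29.3 TPM and at 162 and 97.7 TPM, with adjusted p of 2.28e-05 and 0.0232, and Kit at 11.8 and 12.1 TPM. The leukocyte list fixed earlier had a median of 0.01.

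Gene families counted by name gave further values. Of 44 collagen genes, 39 reached 1 TPM in both libraries, with a summed 8823 TPM. Of 53 keratin genes 18 did, with a median log2 ratio of −0.37. Of 79 ribosomal protein genes 77 did, with a summed 68578 TPM and a median of −0.07, and of 19 Sox genes 12 did, with Sox11 the highest.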
